A study of Arabidopsis thaliana with 16 samples.

How the data were processed

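Transcript levels were measured on Affymetrix ATH1 arrays in leaves of Arabidopsis thaliana, with 1 array for each of 16 pools of 20 plants. The plants were wild type (the accession Col-0) or pft1, a mutant of the Mediator subunit MED25. Mediator is the complex that links transcription factors to RNA polymerase II. Plants were 4 weeks old when their roots were dipped for 15 s in water (mock) or in a suspension of 1e+06 spores per ml of Fusarium oxysporum, a soil fungus that enters through roots. They then went from 8 h to 16 h of light and from 24 °C to 28 °C by day, and leaves were taken 48 h after the dip. Each of the 4 groups, WT mock, pft1 mock, WT infected and pft1 infected, held 4 independent replicates per the labels.

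The deposited table holds ratios made by the authors: each probe set's value is divided, on a linear scale, by its median over the arrays. This was read from the values, since the middle pair of the 16 values averaged 1, within 1e-06, in 22809 of 22810 rows. RMA is named in the submitters' processing notes without a version. The absolute signal is not used here, so whether a probe set lay above background is unknown, and levels of different probe sets cannot be compared. The plan had assumed log2 signal. The ratios were taken to log2 with no pseudocount, and the dividing constant cancels in every difference between groups. Settings of the plan that need signal levels were not run: a filter on dim probe sets, a prior variance with a trend in mean level, and the choice of the brightest probe set per gene.

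The 64 Affymetrix control probe sets were left out of the tests, which leaves 22746. All columns of the table were matched to a sample. Probe sets were named through the platform annotation supplied with the table, with symbols updated by gene identifier through the TAIR10.1 gene table. That gave 13513 probe sets with 1 gene, of which 13436 matched the gene table, 503 with several genes, and 8730 that are unnamed here. Only probe sets with 1 gene were named in the text, and 2 probe sets called in the interaction stay unnamed. The transcript of MED25 was not analysed here, so the genotype labels were not checked by the mutated gene.

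Comparisons were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 16 arrays (12 residual degrees of freedom). There were 5 comparisons: infection in each genotype, genotype under each treatment, and the interaction. Adjusted p-values are from limma's moderated test with Benjamini-Hochberg adjustment over the 22746 probe sets, called at 0.05. Named genes followed a rule: for each comparison, the 8 largest rises and 8 largest falls among called probe sets with 1 gene and no overlap between the groups compared, 20 fixed genes, of which 1 (PDF1.2) had a probe set named here, and the 4 members of smallest p in each called gene list. There were 23 gene lists of 375 genes in all, of which 64 genes had a named probe set. The 11 lists with at least 3 such genes were tested with camera at a preset correlation of 0.01, beside an estimated correlation and fry, and adjusted over the lists. Array-level measures were compared by a two-sided exact permutation test, whose smallest possible p with 4 against 4 arrays is 0.0286. The comparisons, lists, naming rule and first set of alternatives were fixed before the data were examined. The number of arrays limits the precision of every value.

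The steps were tested on simulated data with the real residual spread and shared deviations within replicate numbers, on 22746 probe sets of which 200 were changed. Of those changed by 1 on the log2 scale, 97% were recovered for infection in wild type, 89% for infection in pft1, 90% for genotype under mock, 86% for genotype under infection and 76% for the interaction. Of those changed by 2, at least 96% were recovered in each of these comparisons. The false share among calls was 3.90%, 7.43%, 0%, 0% and 0% in the same order. The simulation drew each probe set independently, so it held no deviations common to many probe sets. Other splits of the real arrays gave up to 767 calls for genotype under infection and 477 for the interaction. The simulated false shares may therefore be too low for the real arrays. The simulated recovery may be too high. More probe sets were changed than the 5 to 161 called in the real comparisons, and the adjustment is stricter when fewer change. In the real data the interaction of AT4G16260, at -2.20 (SE 0.36), was not called (adjusted p = 0.0700). A probe set that was not called is therefore not shown to be unchanged.

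The replicate numbers come from the sample titles. Deviations from the group means were correlated across probe sets between arrays of the same number. For wild type against pft1 under mock, r was 0.32 to 0.57, and under infection 0.59 to 0.70, and each of the 4 arrays correlated best with its own number. The numbers were therefore taken to pair the samples of both genotypes within a treatment. Across treatments same-number r ran from -0.38 to 0.59, so the numbers were not taken to pair mock with infected samples. With numbers 1 and 2 exchanged, which the labels do not give, r across treatments was 0.15 to 0.59, and no fit used that exchange. A fit with a replicate block within treatment (6 residual degrees of freedom) was added for the genotype comparisons and the interaction. It was chosen after this check was seen, and the counts under the planned replicate block were seen in the same step as the check. Other points followed the data too. The 100 splits for the interaction were redrawn once, because the first draw had left out opposite orientations and had fallen below the 5% limit that the second draw met. The test of a constant factor on 1 array was replaced after its first form was seen to be void. The test of pft1 pools that escaped infection was replaced too, since its first form left out the interaction probe sets and so chose probe sets by the value tested. The spread condition on the test of an infected pool was added after its value was seen.

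Alternatives were a replicate block, only the 8 arrays compared, quantile normalization, centring each array on its median, array quality weights, and leaving out each array. Added after seeing the data were the replicate block within treatment (fixed or random), a robust prior variance, 1 value per gene, only probe sets without repeated values, the hybridization control level as a covariate, and the block without the array that stood apart.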

Results

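Leaf transcripts were compared between wild type and pft1 plants, each after a mock root dip or a dip in Fusarium oxysporum spores, with 4 arrays per group. PFT1, also called MED25, is a Mediator subunit known for its part in jasmonate-dependent defence, and the design asks which leaf transcripts respond to infection and which depend on PFT1. Effects are differences between group means of the log2 of the deposited ratios, with the standard error (SE) of the fit and n = 4 arrays per group. Adjusted p-values are limma's with Benjamini-Hochberg adjustment over 22746 probe sets.

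The arrays were alike in their median ratio, from 0.991 to 1.01, except WT mock replicate 1, whose median ratio was 1.12. That array also had the highest ratio of 3-prime to 5-prime control signal, a sign of RNA quality, at 1.3, against 0.918 to 1.15 for the other arrays. These values come from the deposited ratios, already divided by each probe set's median over the arrays. They compare arrays with each other, and the absolute RNA quality is unknown. Hybridization controls, which are added RNAs of fixed amount, were 1.59-fold higher on the pft1 infected than on the WT infected arrays (two-sided exact permutation test p = 0.0286, the smallest that 4 against 4 arrays can give; adjusted p = 0.114 over 8 tests). They were 1.47-fold higher on pft1 infected than on pft1 mock arrays, with the same p.

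**Figure D1:**
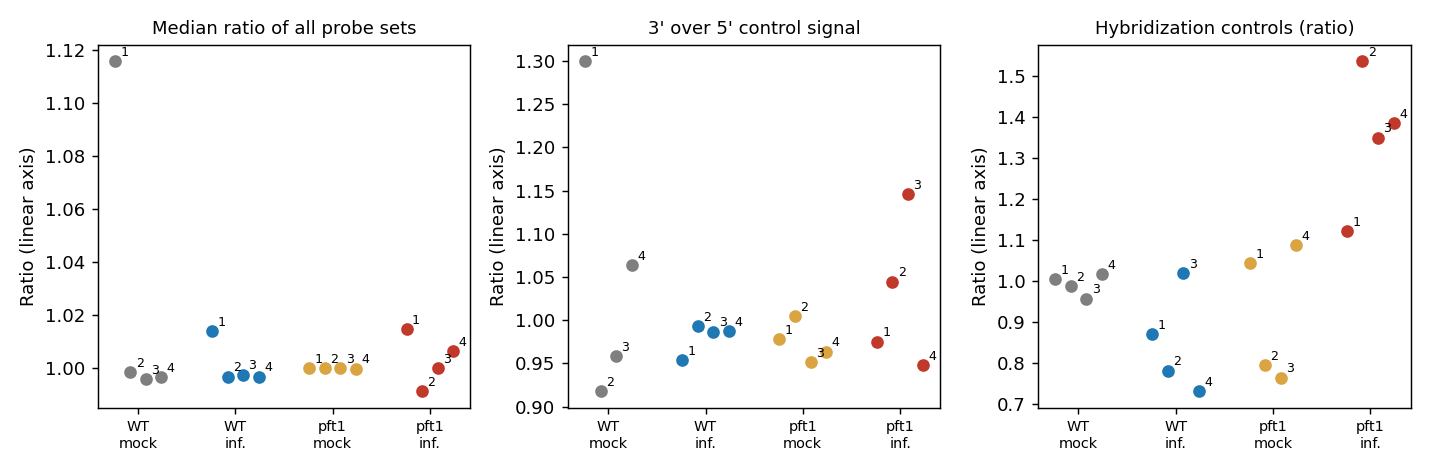
Median ratio of all probe sets, ratio of 3-prime to 5-prime control signal, and level of the hybridization controls for the 16 arrays by group; each point is 1 array, marked with its replicate number. Each is a linear ratio made from values divided by the probe set's median over the arrays, so none is an absolute level. WT mock replicate 1 lies apart in the left and middle panels, at 1.12 and 1.3, and the pft1 infected arrays lie at 1.12 to 1.54 in the right panel.

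The first comparison asked how wild-type leaves responded to infection of the roots. The plant defensins PDF1.2 (AT5G44420) and PDF1.2b (AT2G26020), antifungal peptides used as markers of the jasmonate and ethylene response, rose most. PDF1.2 rose by 6.02 (SE 0.56, 64.9-fold, adjusted p = 6.14e-05) and PDF1.2b by 5.15 (SE 0.57, 35.5-fold, adjusted p = 0.000473). JMT, which makes methyl jasmonate, rose by 1.89 (SE 0.14, 3.71-fold, adjusted p = 1.22e-05). AT3G16530, a lectin-like gene, rose by 2.21 (SE 0.32) and AT4G16260, a glucanase-like gene, by 2.20 (SE 0.26). SAG29, a sugar transporter of senescing leaves, fell by 2.20 (SE 0.36, 4.59-fold, adjusted p = 0.0197).

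Other named risers in wild type were AT4G24350 at 1.69 (SE 0.14), AT1G14120 at 1.25 (SE 0.20) and MSRB6, a methionine sulfoxide reductase, at 1.15 (SE 0.16). AT1G25530 fell by 0.55 (SE 0.09). In total 21 probe sets rose and 2 fell (17 and 1 by at least 2-fold), and 1372 had an unadjusted p under 0.05. None of the 23 overlapped between groups, whereas 2.80% of all probe sets did not overlap, against 2.86% by chance. PDF1.2 ratios on the WT infected arrays were 81.1 to 245, against 0.929 to 1.27 on the WT mock arrays other than replicate 1, where the ratio was 10.3. PDF1.2b is read by a probe set of a type that can cross-hybridize.

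Of the jasmonate and ethylene defence branch, 4 members were measured. PDF1.2 and PDF1.2b rose (2 members, and also 2 adjusted over the list alone), while OSM34 was at 0.16 (SE 0.23) and LCR67 (PDF1.1) at -0.05 (SE 0.08), neither past the threshold. OSM34 was at 0.02 without WT mock replicate 2, at 0.34 without WT mock replicate 1 and at 0.08 with the hybridization covariate, and LCR67 was at 0.03 without WT mock replicate 1. The list was called by camera (adjusted p = 4.6e-07) and by fry (adjusted p = 0.00268), and not with an estimated correlation (adjusted p = 0.0742 with an estimated correlation). The other 10 tested lists were not called by camera in this comparison. The salicylate response (mean 0.04) and the 8 measured Mediator subunits other than MED25 (mean -0.05) were not called in any of the 5 comparisons. Of the 22 members of the salicylate list only 3 were measured (SAG101, GRX480 and WRKY53). They cannot show whether the salicylate response as a whole changed. The other 12 of the 23 lists had too few named probe sets for a test.

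Under quantile normalization, which replaces the extreme ratios of an array by a mean over arrays, PDF1.2 was at 2.62 (adjusted p = 0.0572), PDF1.2b at 2.06 (adjusted p = 0.335), SAG29 at -2.41 (adjusted p = 0.0568) and AT1G25530 at -0.60 (adjusted p = 0.195), none past the threshold. On only the 8 wild-type arrays, AT1G14120, AT1G25530, AT3G16530, AT4G16260, MSRB6 and PDF1.2b were not past it (adjusted p = 0.055 to 0.166). Without WT mock replicate 1, PDF1.2 was at 6.82 and PDF1.2b at 5.96. AT1G14120 did not pass without any 1 of WT mock replicates 2, 3 and 4 and WT infected replicates 1, 2 and 3 (adjusted p up to 0.114), and SAG29 without any 1 of replicates 1, 3 and 4 of WT mock and of WT infected (adjusted p up to 0.114). AT1G25530 did not pass without any 1 of the WT mock arrays, pft1 mock replicates 2 and 4 and WT infected replicates 2, 3 and 4 (adjusted p up to 0.162), nor with the hybridization covariate (adjusted p = 0.128). Without WT infected replicate 3 there were 15 calls, and with 1 value per gene 13.

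The second comparison asked the same of pft1 leaves. The transcripts that rose were AT3G05730, a defensin-like gene, by 1.45 (SE 0.16, 2.73-fold, adjusted p = 0.00164), AT1G66100, a thionin, by 1.38 (SE 0.16, 2.59-fold, adjusted p = 0.00164), and AT5G48430, a protease-like gene, by 1.37 (SE 0.10, 2.59-fold, adjusted p = 2.25e-05). AT3G22060 rose by 1.04 (SE 0.17) and AT1G06830, a glutaredoxin-like gene, by 0.74 (SE 0.12). AT1G25530 fell by 0.70 (SE 0.09) and AT5G51890, a peroxidase, by 0.47 (SE 0.08). PDF1.2 was at 0.11 (SE 0.56, adjusted p = 0.977) in pft1, and at -0.31 (SE 0.88) with the hybridization covariate.

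In total 6 probe sets rose and 4 fell in pft1 (5 and 1 by at least 2-fold), with 1896 at an unadjusted p under 0.05. Of the 4 measured members of the pattern-triggered immunity list, none passed over all probe sets and 1 (PUB22, a ubiquitin ligase) adjusted over the list alone. PUB22 was at 0.62 (SE 0.20), WRKY22 at 0.64 (SE 0.28), BIK1 at 0.34 (SE 0.15) and PUB23 at 0.34 (SE 0.27). With the level of the hybridization controls, which were higher on pft1 infected arrays, as a covariate they were at 0.55 (SE 0.32), 0.31 (SE 0.43), 0.09 (SE 0.23) and 0.12 (SE 0.43) in this order. Without pft1 mock replicate 2 BIK1 was at 0.22 and PUB23 at 0.21, and without pft1 infected replicate 3 WRKY22 was at 0.39. The list was called by camera (adjusted p = 0.00919), and not with an estimated correlation (adjusted p = 0.315 with an estimated correlation). The other 10 lists were not called by camera. The heat shock list (mean -0.19) was called by fry alone (adjusted p = 0.0189, against 0.0668 by camera, and adjusted p = 0.282 with an estimated correlation), with none of its 4 members past the threshold over all probe sets and 1 (ROF2 at -0.51, SE 0.15) adjusted over the list alone.

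The hybridization controls were higher on pft1 infected arrays, and with their level as a covariate 1 probe set passed, AT5G48430, while the other 6 named genes did not (adjusted p = 0.352 to 0.77). Their values were then 1.52 (SE 0.25) for AT3G05730, 1.3 (SE 0.25) for AT1G66100, 1.09 (SE 0.27) for AT3G22060, 0.81 (SE 0.19) for AT1G06830, -0.71 (SE 0.15) for AT1G25530 and -0.38 (SE 0.12) for AT5G51890, so the calls ended mostly through larger standard errors (median 0.22, against 0.14 before). On only the 8 pft1 arrays AT1G06830, AT1G25530, AT3G22060 and AT5G51890 did not pass (adjusted p = 0.113 to 0.177). With array weights AT1G06830, AT3G22060 and AT5G51890 did not (adjusted p = 0.0548 for each). AT5G51890 did not pass after centring each array (adjusted p = 0.0645), nor AT3G22060 after quantile normalization (adjusted p = 0.0723) or with the random replicate block within treatment (adjusted p = 0.0573). Counts were 17 without WT mock replicate 1 and 16 without WT infected replicate 4. They were 6 without WT mock or WT infected replicate 3, 5 without WT infected replicate 1, 4 without WT mock replicate 2, pft1 mock replicate 3 or pft1 infected replicates 1 or 3, and 3 without pft1 mock replicates 1 or 2. AT1G25530 did not pass without pft1 mock replicates 1 or 2 or pft1 infected replicate 3 (adjusted p up to 0.0708). AT1G06830 did not without 11 single arrays (all but WT mock 1 and 4, WT infected 2 and 4, and pft1 infected 2), AT3G22060 without 12 (all but WT mock 1 and 4, WT infected 4 and pft1 infected 3) and AT5G51890 without 13 (all but WT mock 1, pft1 mock 4 and WT infected 4), with adjusted p up to 0.181. The pattern-triggered immunity list was not called without pft1 mock replicate 2 or pft1 infected replicates 2 or 3 (adjusted p up to 0.0791).

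The third comparison asked what differed between pft1 and wild type after a mock dip. QQS (AT3G30720), a gene known for its effect on leaf starch, was 5.17-fold higher in pft1 (2.37, SE 0.17, adjusted p = 7.63e-06). AT5G52390 was higher by 1.63 (SE 0.30) and AT4G25780 by 1.06 (SE 0.16). The thionin AT1G66100 was 4.1-fold lower in pft1 (-2.04, SE 0.16, adjusted p = 1.18e-05), AT5G37990, a methyltransferase-like gene, 4.31-fold lower (-2.11, SE 0.29), and AT4G01390 3.73-fold lower (-1.90, SE 0.21). PDF1.2 was at -1.18 (SE 0.56, adjusted p = 0.755), and at -0.38 without WT mock replicate 1.

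Other transcripts higher in mock pft1 were AT3G19620 at 1.00 (SE 0.21), AT4G13180 at 0.88 (SE 0.18), the defensin-like gene LCR68 at 0.49 (SE 0.10) and AT1G14580 at 0.44 (SE 0.09). Lower ones were AT1G54020 at -1.93 (SE 0.38), the peroxidase AT2G37130 at -1.67 (SE 0.33), AT1G62510 at -1.46 (SE 0.17), the receptor kinase-like gene AT4G27300 at -1.38 (SE 0.19) and AT5G33370 at -1.30 (SE 0.16). In total 23 probe sets were higher and 89 lower (7 and 38 by at least 2-fold), with 1526 at an unadjusted p under 0.05. With the replicate block within treatment the counts were 107 and 381, or 488 in all, which held all 112. Without WT mock replicate 1 they were 75 in all, of which 68 were among the 112, and without pft1 mock replicates 1, 2 and 3 they were 64, 64 and 66.

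By camera 4 lists were lower in mock pft1, with adjusted p = 0.0108 for the epidermal list and 0.0184 for each of the root markers, pattern-triggered immunity and the jasmonate and ethylene defence branch. None was called with an estimated correlation, with adjusted p = 0.218 for the epidermal list, 0.294 for the root markers, and 0.349 for each of the other 2 with an estimated correlation. Of the 3 measured root markers, PYK10 (a myrosinase-type glucosidase of ER bodies) fell by 0.91 (SE 0.17, adjusted p = 0.0212), also adjusted over the list alone, while the root-hair expansins EXPA7 and EXPA18 were at -0.08 (SE 0.13) and -0.14 (SE 0.10), or at -0.02 and -0.09 without WT mock replicate 1, and EXPA7 at -0.16 without WT mock replicate 2. The 3 measured epidermal markers were FAMA (listed as FMA) at -0.58 (SE 0.15) and SPCH at -0.32 (SE 0.11), both regulators of stomata, and TRY, a trichome regulator, at -0.35 (SE 0.30), or at -0.08 without WT mock replicate 2 and -0.56 without WT mock replicate 1. None of these 3 passed over all probe sets and 2 did adjusted over the list alone. In the pattern-triggered immunity list PUB23 was at -0.95 (SE 0.27), the 1 of 4 members that passed adjusted over the list alone. In the jasmonate and ethylene defence branch none of the 4 members passed, nor adjusted over the list alone. With the replicate block within treatment FAMA passed (adjusted p = 0.00391), as did PUB23 (adjusted p = 0.0191). With that block and without WT mock replicate 1 FAMA passed (adjusted p = 0.0253) and TRY did (adjusted p = 0.0239), while PUB23 did not (adjusted p = 0.115). On all arrays TRY did not pass with that block, nor with it random (adjusted p = 0.549). With the block random FAMA (adjusted p = 0.0123) and PUB23 (adjusted p = 0.0411) passed. FAMA also passed with array weights (adjusted p = 0.0421).

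Single arrays decided some of these calls. AT5G52390 did not pass without any 1 of WT mock replicates 1, 2 and 3 and pft1 mock replicates 1 and 2 (adjusted p up to 0.0779), and PYK10 without any 1 of WT mock replicates 1 and 3 and pft1 mock replicates 2, 3 and 4 (adjusted p up to 0.0863). AT1G54020 did not without 8 arrays (WT mock 1, 3 and 4, pft1 mock 2, 3 and 4, and WT infected 3 and 4; adjusted p up to 0.123), and AT1G14580 without 9 (WT mock 3 and 4, all pft1 mock, WT infected 2 and 3, and pft1 infected 3; adjusted p up to 0.142). AT2G37130 did not without 11 (all but WT mock 2, pft1 mock 4, WT infected 1, and pft1 infected 1 and 4; adjusted p up to 0.108), and AT4G13180 without 12 (all but replicates 1 and 4 of WT infected and of pft1 infected; adjusted p up to 0.176). AT3G19620 did not without 13 (all but pft1 infected 1, 3 and 4; adjusted p up to 0.181), and LCR68 without 15 (all but WT mock 1; adjusted p up to 0.173). On only the 8 mock arrays these 8 genes did not pass (adjusted p = 0.0543 to 0.252), and after quantile normalization AT5G52390 and PYK10 did not (adjusted p = 0.0638 and 0.0572). With the hybridization covariate there were 72 calls, and AT1G54020, AT2G37130, AT3G19620, AT4G13180, LCR68 and PYK10 did not pass (adjusted p = 0.0506 to 0.116), at -1.83 (SE 0.39), -1.54 (SE 0.33), 1.04 (SE 0.22), 0.83 (SE 0.19), 0.47 (SE 0.11) and -0.90 (SE 0.18) in this order. AT1G54020 and AT3G19620 did not pass with the replicate block across treatments (adjusted p = 0.0517 and 0.0614), nor AT2G37130 with a robust prior variance (adjusted p = 0.0529), nor AT3G19620, AT4G13180 and LCR68 with 1 value per gene (adjusted p = 0.0510 to 0.0541). Of the lists, the defence branch was not called without WT mock replicate 1 (adjusted p = 0.0582), the epidermal list without WT mock replicate 2 (adjusted p = 0.073), the root markers without WT mock replicate 3 (adjusted p = 0.089), and pattern-triggered immunity without WT mock replicate 3 or pft1 mock replicate 2 (adjusted p up to 0.164).

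The fourth comparison set infected pft1 against infected wild type. PDF1.2 was 136-fold lower in infected pft1 (-7.09, SE 0.56, adjusted p = 4.98e-06) and PDF1.2b 81.2-fold lower (-6.34, SE 0.57, adjusted p = 2.23e-05). Under quantile normalization PDF1.2 was at -3.64 (adjusted p = 0.00161) and PDF1.2b at -3.27 (adjusted p = 0.00681). JMT was at -1.13 (SE 0.14, adjusted p = 0.000523). AT4G16260 was 5.12-fold lower (-2.36, SE 0.26) and AT3G16530 4.65-fold lower (-2.22, SE 0.32). QQS was again higher, 4.99-fold (2.32, SE 0.17, adjusted p = 2.58e-06). AT5G03350, a lectin-like gene that responds to salicylate, was 3.08-fold higher (1.62, SE 0.21), and AT3G48080, a paralogue of the immune regulator EDS1, was 1.79-fold higher (0.84, SE 0.15).

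**Figure D2:**
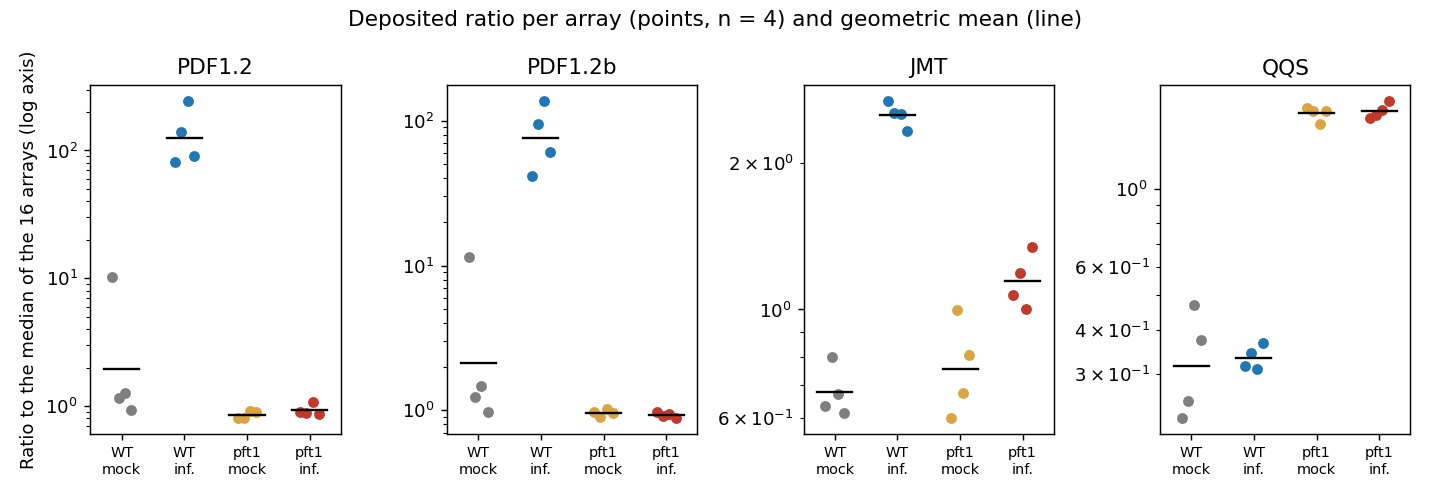
Deposited ratios (log axis, relative to the median of the 16 arrays) of PDF1.2, PDF1.2b, JMT and QQS by group; each point is 1 array and each line the geometric mean of 4 arrays. PDF1.2 lies at 81.1 to 245 in WT infected and at 0.862 to 1.07 in pft1 infected, and QQS lies at 1.53 to 1.77 in both pft1 groups and at 0.225 to 0.470 in both wild-type groups.

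Other transcripts lower in infected pft1 were AT3G23550 at -3.10 (SE 0.62), AT1G54020 at -2.31 (SE 0.38), AT4G24350 at -2.23 (SE 0.14) and AT5G33370 at -2.06 (SE 0.16). Other higher ones were AT5G52390 at 1.70 (SE 0.30), AT5G55450 at 1.08 (SE 0.23), AT3G22240 at 1.04 (SE 0.16), the protease inhibitor-like AT1G17860 at 0.76 (SE 0.14) and the calmodulin-like AT2G41090 at 0.75 (SE 0.13). In total 30 probe sets were higher and 131 lower (11 and 58 by at least 2-fold), with 1618 at an unadjusted p under 0.05. With the replicate block within treatment the counts were 179 and 452, or 631 in all, which held all 161. The hybridization controls were 1.59-fold higher on these pft1 arrays, and with their level as a covariate 18 probe sets passed, all of them among the 161. The covariate ended 10 of the 16 named calls (adjusted p = 0.194 to 0.971), as the median SE of these genes went from 0.22 to 0.37. AT1G54020 was then at -2.83 (SE 0.66), AT3G16530 at -2.57 (SE 0.57), AT3G23550 at -3.44 (SE 1.11), AT5G55450 at 1.11 (SE 0.42), AT3G22240 at 0.94 (SE 0.28) and AT1G17860 at 0.75 (SE 0.25). The values that fell most were those of AT5G03350 at 1.06 (SE 0.33), AT5G52390 at 1.17 (SE 0.51), AT3G48080 at 0.51 (SE 0.25) and AT2G41090 at 0.55 (SE 0.22).

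By camera 3 lists were lower in infected pft1, the jasmonate and ethylene defence branch (adjusted p = 6.78e-08), the flavonoid and anthocyanin list (adjusted p = 5.13e-05) and the epidermal markers (adjusted p = 0.0232). None was called with an estimated correlation, with adjusted p = 0.0516, 0.167 and 0.169 in this order. By fry the first was called (adjusted p = 0.000294), and the flavonoid and epidermal lists were not (adjusted p = 0.102 and 0.116). In the jasmonate and ethylene defence branch PDF1.2 and PDF1.2b were lower, also adjusted over the list alone, OSM34 was at -0.32 (SE 0.23; -0.13 without pft1 infected replicate 2 and -0.07 with the hybridization covariate) and LCR67 at 0.01 (SE 0.08). In the flavonoid and anthocyanin list the 4 measured members were DFR at -1.11 (SE 0.32), UF3GT at -1.08 (SE 0.41), AT4G14090 at -1.10 (SE 0.43) and AT5MAT at -0.72 (SE 0.29). None of them passed over all probe sets and all 4 did adjusted over the list alone. The epidermal markers were at -0.37 (SE 0.15) for FAMA, -0.52 (SE 0.30) for TRY and -0.15 (SE 0.11) for SPCH, and none passed either way. TRY was at -0.34 without WT infected replicate 1, and SPCH at -0.09 without that array and at -0.23 without pft1 infected replicate 3. Of the root markers, not called as a list here, PYK10 was at -0.99 (SE 0.17), EXPA7 at 0.22 (SE 0.13) and EXPA18 at 0.19 (SE 0.10), the last 2 not past the threshold. With the replicate block within treatment DFR (adjusted p = 0.0120), UF3GT (adjusted p = 0.0344), FAMA (adjusted p = 0.0425) and TRY (adjusted p = 0.0336) passed. With that block random DFR passed (adjusted p = 0.0301), and UF3GT (adjusted p = 0.12), FAMA (adjusted p = 0.128) and TRY (adjusted p = 0.319) did not. With the block fixed and without WT mock replicate 1 AT5MAT passed too (adjusted p = 0.0472). With the hybridization covariate FAMA was at 0.02 (SE 0.23) and TRY at 0.01 (SE 0.51), and the flavonoid members DFR at -0.89 (SE 0.56), UF3GT at -0.60 (SE 0.72), AT4G14090 at -0.68 (SE 0.75) and AT5MAT at -0.24 (SE 0.49).

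Without WT infected replicate 2 there were 104 calls. AT3G48080 did not pass without WT infected replicate 3 (adjusted p = 0.0527), AT1G17860 without WT infected replicate 3 or pft1 infected replicate 1 (adjusted p up to 0.0582), and AT3G23550 without any 1 of WT infected replicates 2 and 3 and the pft1 infected arrays (adjusted p up to 0.117). AT5G55450 did not without 11 arrays (all but WT mock 1, pft1 mock 1 and 3, WT infected 4 and pft1 infected 3; adjusted p up to 0.147). After quantile normalization AT3G23550 (adjusted p = 0.0576), AT5G55450 (adjusted p = 0.0991) and AT5G52390 (adjusted p = 0.196) did not pass. With array weights AT5G52390 and AT5G55450 did not pass (adjusted p = 0.052 and 0.0837), and on only the 8 infected arrays AT1G17860 and AT5G55450 did not (adjusted p = 0.0728 and 0.142), nor did AT5G55450 with a robust prior variance (adjusted p = 0.0507). The epidermal list was not called without WT infected replicates 1 or 4 or pft1 infected replicate 2 (adjusted p up to 0.205).

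Differences between the genotypes were compared between the treatments. Of the 206 probe sets called under either treatment, 67 were called under both and 204 had the same sign under both. Of the 67, 10 were higher and 57 lower in pft1 under both, against 0.030 and 0.51 for independent lists. Across all probe sets the genotype effects correlated at r = 0.51. Turning the signs of genotype within the replicate pairs gave 64 arrangements, and the highest r of the others was 0.48 (covariance 0.019, against a median of 0.0014). With 1 array left out r was 0.43 to 0.56. With the hybridization covariate r was 0.33, and 11 of the 64 arrangements fitted in that way, the real one included, gave as high an r (up to 0.56), so r was then not above that of other arrangements. Probe sets are not independent replicates, so no p-value is given.

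**Figure D3:**
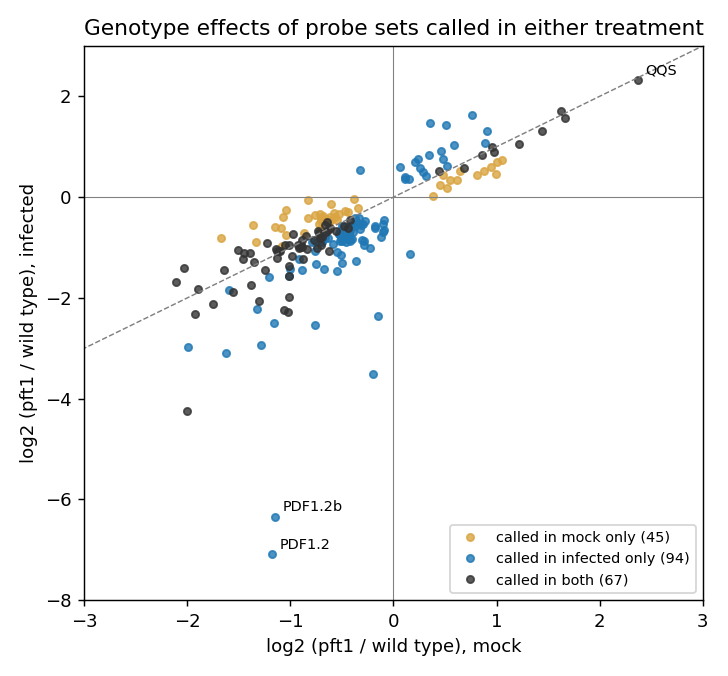
Difference between pft1 and wild type (log2) under mock (horizontal axis) and under infection (vertical axis) for the 206 probe sets called in either treatment; each point is 1 probe set, coloured by where it was called, and the dashed line marks equal effects. Of these points 67 were called in both treatments in the same direction, and PDF1.2 and PDF1.2b lie far below the line, at -7.09 and -6.34 under infection.

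The last comparison asked whether the response to infection differed between genotypes. It called 5 probe sets, all with a lower infection effect in pft1 than in wild type. PDF1.2 had an interaction of -5.91 (SE 0.79, adjusted p = 0.0130), PDF1.2b of -5.19 (SE 0.80, adjusted p = 0.0426) and JMT of -1.30 (SE 0.20, adjusted p = 0.0421). The other 2 are unnamed here, with interactions of -2.24 (SE 0.27, adjusted p = 0.0125) and -3.31 (SE 0.44, adjusted p = 0.0130). At an unadjusted p under 0.05 there were 729 of 22746, fewer than the 5% that would be there without any effect.

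Of the 21 probe sets that rose in infected wild type, 18 were lower in infected pft1 than in infected wild type past the threshold. Some of these were already called lower in mock pft1, such as AT4G24350 at -1.06. The count therefore does not measure a smaller response to infection. The rise in wild type and the comparison of infected plants both use the same WT infected arrays. With 2 of these arrays set against mock and the other 2 against pft1, in 6 ways, 8 to 13 probe sets rose, and 8 to 10 of them were lower in infected pft1 past the threshold. A simulation without effects gave 0 of 21, but few probe sets are called at all in such data. Independent lists would share 0.121, but these lists are not independent, as they share arrays. Neither value is a baseline for the 18. In pft1 1 of the 21 (AT3G05730) passed the threshold, and the median of the 21 was 0.48, against 1.3 in wild type. The 21 were chosen by their rise in wild type, which by itself favours a higher median there. Infection effects correlated at r = 0.50 across probe sets between genotypes, but splitting the 8 replicate pairs in other ways gave a median r of 0.54, so this value was not above that of shared replicate deviations (covariance 0.018, against a median of 0.013). With the hybridization covariate r was 0.25.

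By camera the jasmonate and ethylene defence branch (adjusted p = 5.56e-05) and the flavonoid and anthocyanin list (adjusted p = 0.04999) had lower infection effects in pft1. With an estimated correlation they were adjusted p = 0.205 and 0.453. In the first, PDF1.2 and PDF1.2b passed over all probe sets and adjusted over the list alone, and in the second no member passed, with DFR at -0.64 (SE 0.45) and AT5MAT at -0.17 (SE 0.41). With 1 array left out DFR ran from -0.92 (without WT infected replicate 3) to -0.33 (without WT infected replicate 2), and AT5MAT was at 0.09 without WT mock replicate 1. With the hybridization covariate DFR was at -0.37 (SE 0.71), UF3GT at -0.01 (SE 0.91), AT4G14090 at -0.35 (SE 0.95) and AT5MAT at 0.40 (SE 0.63). The interaction calls were 1 under quantile normalization, 8 with the replicate block within treatment (all 5 among them) and 0 with the hybridization covariate. Under quantile normalization neither list was called (adjusted p = 0.159 and 0.287), nor the flavonoid list after centring each array (adjusted p = 0.0766) or without 11 single arrays (all but WT mock 4, pft1 mock 1 and 3, WT infected 3 and pft1 infected 4; adjusted p up to 0.305).

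Quantile normalization ended the interactions of PDF1.2 (-2.46), PDF1.2b (-2.10) and JMT (-1.28), with adjusted p = 0.742 to 0.9996. PDF1.2b did not pass with the replicate block across treatments (adjusted p = 0.0903) or with a robust prior variance (adjusted p = 0.0773). Without WT mock replicate 1 there were 5 calls, 4 of them the same probe sets, with PDF1.2 at -6.71, PDF1.2b at -6.01, and JMT at -1.27, not past the threshold (adjusted p = 0.0860). Leaving out WT mock replicate 3 or WT infected replicate 2 left 1 call each, and PDF1.2 did not pass without either (adjusted p up to 0.0514). There were 3 calls without WT mock 4, pft1 mock 4, WT infected 1 or 3, or pft1 infected 1, 2 or 3. JMT did not pass without 11 arrays (all but WT mock 2, pft1 mock 1, 2 and 3, and pft1 infected 4; adjusted p up to 0.139), and PDF1.2b without 15 (all but WT mock 1; adjusted p up to 0.154).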

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

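The tests of pools that escaped infection over all risers and with the covariate, of a constant factor, of values computed apart and of RNA degradation, of replicate numbers across treatments, of exchanged numbers, of WT mock replicate 1 in the interaction, and the redrawn splits of the interaction were chosen only after the result was seen.

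Infection effects differed between the genotypes by the interaction test, by -5.91 for PDF1.2, -5.19 for PDF1.2b, -1.30 for JMT, and -2.24 and -3.31 for 2 unnamed probe sets. If pft1 pools had escaped infection no response would be seen. Over all 21 risers of wild type the median infection effect in pft1 was 0.48 (median SE 0.16, 20 of 21 above 0), against 0.36 at most in the other 34 of 35 splits of the pft1 arrays. With the hybridization covariate it was 0.38 (median SE 0.25, 16 of 21 above 0), against 0.27 at most. The 21 were chosen by the difference between wild-type arrays, and arrays of both genotypes shared deviations within a treatment. A shift shared by the infected arrays of both genotypes would appear in pft1 too. This test therefore cannot decide whether pft1 pools escaped infection, and a weaker infection of pft1 was not tested. The hybridization controls, outside the main measurement, were 1.59-fold higher on pft1 infected than WT infected arrays. With their level as a covariate the median interaction of the 5 was -3.6 (median SE 0.70), against -3.31 before. All 5 calls ended as the SE grew (for PDF1.2 from 0.79 to 1.25). The fit takes the effect of that level from differences within groups. The levels of pft1 infected (1.12 to 1.54) and WT infected arrays (0.730 to 1.02) did not overlap. The values argue only against an effect as large as that seen within groups as the whole cause. They cannot exclude another effect of hybridization between the groups. Leaving out WT mock replicate 1 kept 4 of the 5 past the threshold (JMT at -1.27, against -1.30, adjusted p = 0.0860). In these 4 that array had the highest WT mock ratio (10.3 for PDF1.2, 11.5 for PDF1.2b, 1.60 and 2.32 for the unnamed probe sets). It thus made their rise in wild type smaller, and leaving it out could not weaken these interactions. Its direction argues against that array for these 4, and for JMT the array stays undecided. A need for PFT1 in the induction of the 5 transcripts stays open as a hypothesis.

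WT mock replicate 1 was set apart by a median ratio of 1.12 and by PDF1.2 at 10.3, PDF1.2b at 11.5 and LCR67 at 1.26. A constant factor would repeat 1 ratio to another array often, but the most frequent, compared to 6 significant digits, recurred 6 times, against at least 85 values equal in every deposited digit between any pair of the other arrays. The array shared 0 identical values with any other, as values computed apart from the other arrays could give, and its 3-prime to 5-prime ratio of 1.3 was above the highest of the others (1.15), as RNA degradation could give, so both stay open. An infected pool is undecided: over 23 probe sets the median of its deviation divided by the infection effect was 0.36, under the 0.5 set in advance, but the upper quartile was 0.53, a condition added after the value was seen. No biological explanation was tested.

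Same-numbered arrays of both genotypes deviated together within a treatment, with a mean r of 0.55 over 8 pairs. With the 3-prime to 5-prime difference regressed out the mean r was 0.46, although the pair of mock replicate 1 went from 0.42 to -0.02, and with the hybridization level regressed out it was 0.52, so neither accounts for the pairs as a whole. Numbers that mark the same condition under both treatments are argued against by the lowest same-number r across treatments, -0.38. With numbers 1 and 2 exchanged all 16 values of r across treatments were above 0 (0.15 to 0.59), so a condition shared under other numbers stays open. A shared day, tray or labelling batch within each treatment was not tested, since the labels give none, and no biological explanation was tested.

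Single samples far from the other 3 of their group were found in 13 of 212 groups of named genes, against 10.6 by chance. Besides the 3 above they were AT3G16530 at 0.225, TRY at 1.04 and DFR at 1.03 on pft1 mock replicate 2, AT2G41090 at 0.819 on pft1 mock replicate 3, AT1G66100 at 2.5 and EXPA7 at 1.25 on WT infected replicate 1, AT3G05730 at 1.39 on WT infected replicate 2, AT5MAT at 0.762 on WT infected replicate 3, and AT1G14580 at 0.757 and PYK10 at 1.26 on WT infected replicate 4. Among 16 groups of array measures, 4 had such a sample. Besides the one above these were the median ratios of pft1 mock replicate 4 (0.9999) and WT infected replicate 1 (1.01), and the 3-prime to 5-prime ratio of WT infected replicate 1 (0.954).

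Other splits of the same arrays tested whether chance could give as many calls. For infection in wild type (23 calls) and in pft1 (10), and for genotype under mock (112), 1 of 35 splits, the real one, gave as many. The highest of the others were 1, 0 and 1. These counts stand above those of other splits, but 1 of 35 is the smallest share that the splits can give. The hybridization controls of pft1 infected against pft1 mock arrays reached that limit too (exact permutation test p = 0.0286). Such a share does not tell infection or genotype from other differences between the groups. For genotype under mock, where numbers pair the samples, the highest other of the 8 splits that part all 4 pairs gave 0, and 8 splits are too few for a share under 0.05. For genotype under infection (161) 2 of 35 splits gave as many. The other, with 767 calls, set replicates 1 and 4 of both genotypes against replicates 2 and 3, which points to a structure among the infected samples. It parts none of the pairs, and among the 8 splits that part all 4 pairs the highest other gave 0, but 8 splits are too few for a share under 0.05. With the replicate block within treatment 631 were called. For the interaction (5 calls) 5 of 100 drawn splits gave as many, with up to 477 in another, which also points to a structure of the samples. Chance is therefore not excluded by this count. Only 5 of the drawn splits, the real one included, part all 8 pairs. The highest other of these gave 0, but 5 splits are too few for a share under 0.05. For the gene lists called by camera, 21 of 35 splits gave as many for infection in wild type (1 called, up to 3 in another split), 13 of 35 for infection in pft1 (1, up to 4), 2 of 35 for genotype under mock (4, up to 4), 4 of 35 for genotype under infection (3, up to 4) and 23 of 100 for the interaction (2, up to 4), so chance is not excluded for any of these counts of lists.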

How the results depend on the processing

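The settings added after seeing the data were the blocks within treatment, the robust prior, 1 value per gene, the probe sets without repeated values, the hybridization covariate, and quantile normalization and centring for the lists. No called gene result changed direction, but 7 named gene results that were not called changed sign under some setting, among them LCR67 for infection in wild type (-0.05, and 0.03 without WT mock replicate 1) and the interactions of AT5MAT (-0.17, and 0.09 without that array) and OSM34 (0.05, and -0.12 without that array). The count for infection in wild type (23) was 11 on the 8 arrays compared, 35 with array weights, 13 with 1 value per gene, and 15 to 24 with 1 array left out. For infection in pft1 (10) it was 31 with the replicate block, 4 on the 8 arrays, 23 after quantile normalization, 1 with the hybridization covariate, and 3 to 17 with 1 array left out (17 without WT mock replicate 1). For genotype under mock (112) it was 65 on the 8 arrays, 209 with weights, 488 with the replicate block within treatment, 340 with that block random, 241 with it and without WT mock replicate 1, 72 with the covariate, 44 with 1 value per gene, and 64 to 109 with 1 array left out. For genotype under infection (161) it was 249 with the replicate block, 631 within treatment, 456 with it random, 853 with it fixed and without WT mock replicate 1, 18 with the covariate, 68 with 1 value per gene, and 104 to 196 with 1 array left out. For the interaction (5) it was 1 after quantile normalization, 9 with weights, 8 with the replicate block within treatment, 10 random, 0 with the covariate, and 1 to 5 with 1 array left out. Fewer genes tested and fewer arrays account by construction for lower counts with 1 value per gene and on 8 arrays, and for the other settings the cause was not tested. The replicate number was not taken to pair mock with infected samples, since between each 2 groups across treatments only 2 of 4 arrays correlated best with their own number. The correlation of genotype effects (0.51) was 0.33 with the covariate, 0.43 to 0.56 with 1 array left out, and that of infection effects (0.50) 0.38 to 0.57. Of 52 called gene results 24 kept their call under the planned settings, and of 35 not called 26 moved by over 1.5 times with 1 array left out. None of the 11 called list results kept its call, as all 11 were lost with an estimated correlation and 9 with fry. The filter on dim probe sets, the trended prior and the brightest probe set per gene could not be run on ratios. Signal over background is unknown and limits what low signals can show.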

Other observations

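The test of NAI1 and NAI2 below and the gene families were chosen only after the result was seen.

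Of 10 genes of ER bodies, compartments that store the glucosidase PYK10, 5 had a named probe set, and 3 of these 5 were lower in pft1 past the threshold under both treatments. The group was not a list fixed in advance and had no test as a set. PYK10 was at -0.91 (SE 0.17) under mock and -0.99 (SE 0.17) under infection, and the jacalin-type lectins JAL33 at -0.92 (SE 0.18) and -1.01 (SE 0.18) and JAL34 at -0.84 (SE 0.18) and -1.02 (SE 0.18). Lower transcripts of other ER-body genes in pft1 would extend to NAI1, the regulator of ER bodies, and NAI2, one of their structural proteins. Under infection NAI1 was at -0.62 (SE 0.15, adjusted p = 0.0930) and NAI2 at -0.77 (SE 0.19, adjusted p = 0.101), and with the replicate block within treatment the larger adjusted p was 0.00115. Under mock NAI1 was at -0.32 (SE 0.15, adjusted p = 0.74) and NAI2 at -0.41 (SE 0.19, adjusted p = 0.73), with adjusted p = 0.0714 and 0.0157 with that block. All 5 had values below 0 under both treatments, and also after quantile normalization, which ended the mock calls of PYK10 (adjusted p = 0.0572) and JAL34 (adjusted p = 0.0529). With the hybridization covariate none of the 5 passed under either treatment (PYK10 at -0.90, SE 0.18, under mock and -1.04, SE 0.30, under infection). A wider effect of PFT1 on ER-body genes is a hypothesis, found and tested on the same data.

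Among families of at least 6 named genes with the same symbol stem (42 families), camera called the PDF family higher in infected wild type (2 of 7 members rose, adjusted p = 0.000336; adjusted p = 0.202 with an estimated correlation), and the rps family of organellar ribosomal protein genes lower (8 of 8 members below 0, none past the threshold on its own, adjusted p = 0.00364; adjusted p = 0.711 with an estimated correlation). In infected pft1, 9 of 9 PUB genes and 6 of 6 WRKY genes were above 0, none past the threshold on its own (adjusted p = 0.0281 for each family; adjusted p = 0.187 and 0.316 with an estimated correlation). PUB22, PUB23 and WRKY22 are also in the pattern-triggered immunity list, so these families are not separate evidence. With the hybridization covariate these 3 were at 0.55 (SE 0.32), 0.12 (SE 0.43) and 0.31 (SE 0.43). Over all probe sets the median infection effect was -0.03 in wild type and 0.01 in pft1. The counts of members below or above 0 therefore do not by themselves set a family apart.

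Calls that lie next to each other on chromosomes were counted among 28 of the named genes that differed between genotypes in both treatments. There were 2 pairs within 5 genes of each other, JAL33 with JAL34 and AT5G37990 with AT5G38020, and 87 of 10000 random sets of named genes had as many. Each pair could reflect related neighbouring copies, including cross-hybridization between them, rather than a linked genomic difference, and the count of 2 does not tell these apart.

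QQS differed between the genotypes by 2.37 under mock and 2.32 under infection, with an infection effect in wild type of 0.08 (SE 0.17).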
